A study of Mus musculus with 2 samples.

How the data were processed

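The series holds 2 RNA-seq libraries of bone marrow-derived macrophages from C57BL/6 mice, 1 per group. Per the labels' protocols, marrow cells were grown with 20 ng/mL macrophage colony-stimulating factor and exposed for 24 h to the anti-CD40 antibody FGK45 or to IgG. RNA was extracted with TRIzol, and 1.3 ug per library went into a TruSeq RNA preparation, per the labels' protocols. The submitters' processing notes name HISAT2 2.1.0 as a tool, StringTie without a version, and the mouse build mm10. The gene annotation, the strand setting, the read length and any filters are not given in the sources used here.

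The authors deposited 1 table with a value per gene and library, which was read as FPKM (fragments scaled by transcript length and by library size). The table's header does not name the unit. FPKM was inferred from StringTie in the submitters' processing notes and from column sums of 529103.5 (anti-CD40) and 547362.0 (IgG), which differ between libraries. The values also rise in steps, but TPM, which is FPKM rescaled to a fixed sum per library, would rise in steps too. Columns were assigned by their names, and 0 columns of per-sample values were left unused. All 34714 symbols matched RefSeq genes of GRCm38.p6, the assembly behind mm10, and no symbol occurred more than once. Coordinates are from that annotation. Genes encoded in the mitochondrial genome numbered 0 in the table, and 17186 genes were at 0 in both libraries. An exact 0 can be a failed estimate, so no ratio of FPKM values is given against a gene listed at 0; such genes enter the counts only through the pseudocount.

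Depth was estimated from the steps. For genes with a single annotated transcript and exon, the FPKM multiplied by transcript length should be a whole multiple of a fixed step per library. Within a tolerance of 0.05 steps, 72.2% of 72 low genes of the anti-CD40 library and 86.1% of 36 of the IgG library came out whole, against at most 27.1% and 35.6% with shuffled lengths. The most frequent multiples were 300 and 600 steps. With a step taken as what 0.5 of an aligned base is worth, these are a read of 150 bases and a fragment of 300 bases, and the steps imply 6.16 and 5.58 gigabases of aligned sequence, a ratio of 1.10. The absolute depths and the width of the intervals rest on that reading, and the ratio does not. All of them assume that the unit is FPKM. Approximate fragments per gene were then the FPKM times the median GENCODE (release 21) transcript length times 20.5 (anti-CD40) or 18.6 (IgG) fragments per FPKM and kilobase. From these, 95% exact conditional binomial intervals of the ratio were computed. They cover counting error only, rest on an assumed length per gene, and say nothing of the spread between cultures.

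The measure of difference was the log2 ratio of (FPKM + 1) with anti-CD40 over IgG. It understates the difference of low genes, whereas folds in the text are ratios of the FPKM values themselves. Genes were counted when the higher value was at least 1 FPKM, at 2-fold and at 4-fold. With 1 library per group, no test, p-value or standard error was computed. For 37 gene lists, the median log2 ratio over members at 1 FPKM or more was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart when its median lay outside the central 95% of the random medians, and lists with fewer than 5 such members have no percentile. The percentile describes these libraries and is not a p-value. Several lists share genes, such as 2 between the cytokine and classical activation lists.

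The groups, lists, thresholds, naming rule and main alternatives were fixed before the data were examined. Named genes were Cd40 and the measured members of the PIR list; the 12 highest and 12 lowest ratios among genes at 5 FPKM or more in either library, leaving out model-named, ribosomal and mitochondrial genes and immunoglobulin and T cell receptor segments; up to 4 members of each list with the largest ratio either way; and Gapdh, Actb and B2m. Genes named outside the rule, among them overlapping partners and genes that complete a short count, were chosen after their values were seen.

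The alternatives were pseudocounts of 0.1 and 5 FPKM, centring on the median log2 ratio, rescaling both libraries to TPM-like sums or to their upper quartile, no filter and a filter at 5 FPKM, summing rows that share a symbol, and random lists that were unmatched or matched in 50 bins. Rescaling both libraries to the mean of their sums, removing trends on transcript GC content and on length (lowess span 0.3), and matching random lists on these, were chosen after seeing the data. Transcript length and GC content came from GENCODE and covered 98.6% of the counted genes.

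The count of genes at least 2-fold apart was tested on simulated data for this comparison, with counting noise on 9454 genes. Of 200 genes set 3-fold apart, 86% were counted as at least 2-fold, with 1 unchanged gene counted, and 0% of 200 genes set 1.5-fold apart. For the list percentiles, the measured ratios were used and nothing was simulated. Among 200 lists of 20 genes drawn at random, 3.5% stood apart, and 99% did so when 0.3 was added to their median log2 ratio. The lists and their random counterparts came from the same genes, so a rate near 5% was built in. Lists of genes that vary together were not tested in this way. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.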

Results

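Mouse bone marrow-derived macrophages (strain C57BL/6), grown from marrow cells in macrophage colony-stimulating factor, were profiled by RNA sequencing after 24 h with the anti-CD40 antibody FGK45 or with IgG. CD40 is a receptor of the tumour necrosis factor receptor family that is engaged by CD40 ligand on T cells, and FGK45 is a monoclonal antibody given to activate it. The series title places the comparison in the study of rejected heart grafts and of macrophages that carry PIR-A, the activating paired immunoglobulin-like receptors. Each group held 1 library, so no difference has a replicate check, no p-value was computed, and genes are described only as higher or lower with anti-CD40. The deposited FPKM values rise in steps from which about 6.16 gigabases of aligned sequence follow for the anti-CD40 library and 5.58 gigabases for the IgG library. At that depth, the median gene at 1 FPKM or more rested on about 329 fragments with anti-CD40 and 267 with IgG. Intervals given with fold differences are 95% exact conditional binomial intervals on such approximate fragment numbers and cover counting error only.

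The first question was how far the transcriptome of macrophages differed between anti-CD40 and IgG. The median log2 ratios of immediate early genes, classical activation markers, NRF2 targets and genes of the unfolded protein response stood above those of random lists, and the median of the type I interferon response stood below. Of members at 1 FPKM or more, 22 of 22, 8 of 10, 14 of 19, 16 of 21 and 7 of 41 in turn lay above the median of all genes. Cd40 itself lay close to the median of all genes. Among the PIR receptors, Pirb lay furthest from it, at -0.26 on the log2 scale. Of 34714 genes in the table, 9591 reached 1 FPKM in at least 1 library. Among these, 24 were at least 2-fold higher with anti-CD40 and 30 were at least 2-fold lower on the log2(FPKM + 1) scale. At 4-fold, 1 gene was higher (Gm20716) and 4 were lower (H2aw, Neat1, Gm38733 and Adnp), and of these Gm20716 and Adnp overlap each other in the genome. H2aw overlaps Trim17, a gene that was higher with anti-CD40. Gm20716 had 5.46 FPKM with anti-CD40 and was listed at 0 with IgG, so it passes only through the pseudocount and has no fold of its own. The same holds for 2 of the genes past 2-fold, Pcdhgb4, listed at 0 with IgG, and Plpp6, listed at 0 with anti-CD40. Across the 9101 genes at 1 FPKM or more in both libraries, the Pearson correlation of log2(FPKM + 1) was 0.989, with genes not being independent replicates. Their median log2 ratio on the FPKM + 1 scale was 0.12, a shift toward anti-CD40, and the median ratio of their FPKM values was 1.11. Of the 9591 genes, 94.5% lay within 1.5-fold of the median log2 ratio. Relative to it, 13 genes were at least 2-fold higher and 54 lower. The split was 30 higher and 24 lower with both libraries rescaled to the mean of their sums, an alternative chosen after seeing the data, and 15 higher and 54 lower after upper-quartile scaling. Rescaling to TPM-like sums gave 61 higher and 41 lower, but it also multiplies the values by 1.89 and 1.83, so that the pseudocount and the filter of 1 weigh less. In 100 draws with counting noise alone, the highest counts were 4 genes higher and 2 lower, but the spread between cultures is not part of such draws.

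**Figure D1:**
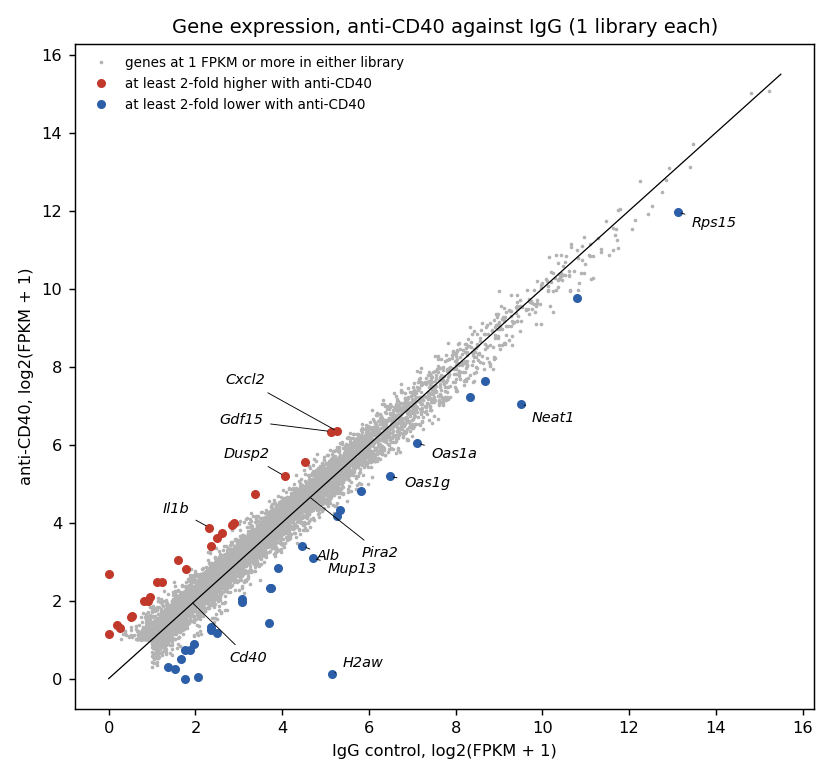
Each point is a gene at 1 FPKM or more in either library, with log2(FPKM + 1) in the IgG library on the horizontal axis and in the anti-CD40 library on the vertical axis; the line marks equal values. The 24 genes at least 2-fold higher with anti-CD40 are red, the 30 at least 2-fold lower are blue, and Cd40 and Pira2 lie in the grey band near the line.

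Cd40 and the PIR receptors, named in the series title, were compared next. Cd40 (chromosome 2, 165055614 to 165071654, GRCm38) stood at 3.01 FPKM with anti-CD40 and 2.67 with IgG. That is 1.13-fold higher, with an interval from 0.785 to 1.64, and the log2 ratio of 0.13 is equal to the median shift to within 0.01. Pira2 (chromosome 7, 3836808 to 3845104) had 24.8 and 23.1 FPKM, a 1.07-fold difference with an interval from 0.993 to 1.16. Pira1 had 21.1 against 20.3 FPKM and Lilra6 had 2.03 against 1.69. The summed values of Pira1, Pira2 and Lilra6 were 48.0 FPKM with anti-CD40 and 45.1 with IgG, or 1.06-fold. Gm14548 and Gm15448, listed here under model names, lie between Pira1 and Lilra6 on chromosome 7 and are not part of that sum. They had 15.2 against 12.6 and 3.88 against 3.56 FPKM. Gm14548 was 1.21-fold higher with an interval from 1.07 to 1.36, and Gm15448 1.09-fold with an interval from 0.857 to 1.39. Pirb, the inhibitory partner receptor (chromosome 7, 3712505 to 3720382), was far more abundant, at 280 FPKM with anti-CD40 and 307 with IgG. Its fold was 0.911, with an interval from 0.894 to 0.928. The leukocyte immunoglobulin-like receptor genes Lilrb4a and Lilr4b had 579 against 553 and 422 against 378 FPKM. The intervals on their folds ran from 1.02 to 1.07 and from 1.09 to 1.15. Lilra5 was near the floor, at 0.031 and 0.030 FPKM.

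The 8 members of the PIR list at 1 FPKM or more had a median log2 ratio of 0.10, at percentile 56.6 of random lists matched on expression, and none was 2-fold apart. Once the median shift is subtracted, Pira1, Pira2, Gm15448 and Lilrb4a turn from slightly higher to slightly lower, as they do after upper-quartile scaling. After alternative names of a gene were merged, the 22 listed symbols led to 9 measured genes, so the remainder is not a count of missing genes. The genes of this cluster are near-identical copies, so the value of a single member is uncertain. A difference of a few percent in these genes was not detectable with 1 library per group.

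**Figure D2:**
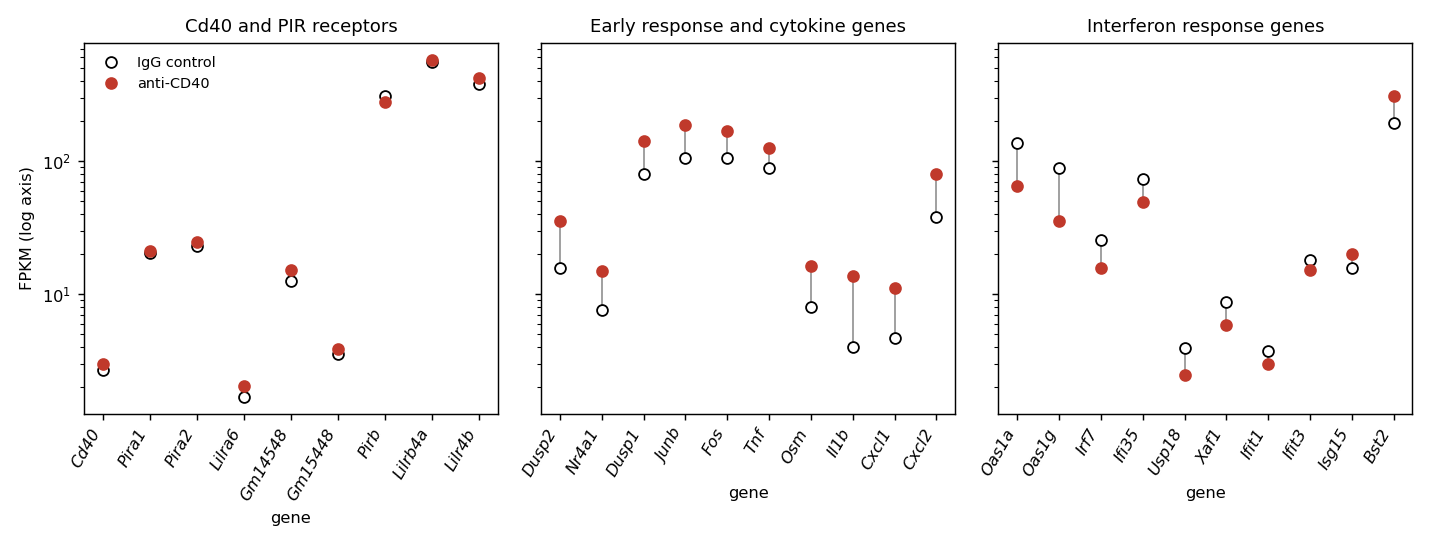
FPKM (log axis) of single genes in the IgG library (open circles) and the anti-CD40 library (red circles), 1 library each, with a line joining the pair. PIR receptors nearly coincide, the early response and cytokine genes shown are higher with anti-CD40, and most interferon genes shown are lower, with Isg15 and Bst2 higher. The cytokine and chemokine genes shown are among the members of their lists with the largest ratios, and neither list stood apart as a whole. Fos, Ifi35, Usp18, Xaf1, Ifit1, Ifit3 and Isg15 were chosen for the plot after their values were seen.

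Both libraries were taken after 24 h of exposure, and no earlier time was sampled. Immediate early genes, which cells transcribe within minutes of a stimulus, formed the list with the highest median. All 22 of its members at 1 FPKM or more lay above the median of all genes, with a list median of 0.60 against 0.12, above all 10000 random lists (percentile 100). Dusp2, a phosphatase acting on MAP kinases (chromosome 2, 127336159 to 127338377), stood at 35.5 FPKM with anti-CD40 and 15.7 with IgG, 2.27-fold higher with an interval from 2.04 to 2.53. The orphan nuclear receptor Nr4a1 had 15.0 against 7.63 FPKM and the MAP kinase phosphatase Dusp1 had 141 against 79.7. Junb, a subunit of the AP-1 transcription factor, had 186 against 106 FPKM, 1.75-fold higher with an interval from 1.68 to 1.82. Dusp2 was the 1 member past 2-fold.

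The list of markers of classical, inflammatory macrophage activation was also higher, with a median log2 ratio of 0.39 over 10 members (percentile 99.96) and 8 of them above the median of all genes. Of its 20 measured members, the other 10 were below 1 FPKM and did not enter, among them Nos2, Il12b and Il6. Il1b, which encodes interleukin-1 beta (chromosome 2, 129364569 to 129371164), had 13.6 FPKM with anti-CD40 and 4.0 with IgG, 3.41-fold higher with an interval from 2.73 to 4.28. Tnf had 125 against 89.1 FPKM, the itaconate-producing enzyme Acod1 had 5.38 against 3.13, and the scavenger receptor Marco had 14.0 against 10.3. The neutrophil-attracting chemokines Cxcl1 and Cxcl2 were 2.38-fold (interval 1.85 to 3.13) and 2.12-fold (1.97 to 2.28) higher. Their levels were 11.1 against 4.65 FPKM and 79.99 against 37.7. Cxcl16 had 192 against 151 FPKM, and Ccl2 3.13 against 2.17 with an interval on its fold from 0.905 to 2.28. The chemokine list as a whole, with 10 members and a median of 0.25, did not stand apart (percentile 95.3).

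Of 25 inflammatory cytokines, 11 reached 1 FPKM, and their median of 0.11 was at percentile 53.8. Osm, the gene of oncostatin M, had 16.2 against 8.01 FPKM and Il10 had 3.30 against 2.42. Of genes often read as signs of strong activation, Il12b had 0.17 and 0.13 FPKM, Nos2 was at 0.027 FPKM with anti-CD40 and listed at 0 with IgG, and Il6 was listed at 0 in both libraries, which can be a failed estimate. These 3 were singled out after their values were seen. NF-kB subunits and feedback targets had a median of 0.17 over 27 genes (percentile 78.9), with 21 above the median of all genes. Among them the deubiquitinase Tnfaip3 had 8.6 against 4.03 FPKM, a 2.14-fold difference with an interval from 1.79 to 2.55 that stays under 2-fold on the log2(FPKM + 1) scale. Ier3 had 27.9 against 16.8 FPKM, mitochondrial superoxide dismutase Sod2 18.9 against 11.4, and Bcl2a1a, which has near-identical copies, 4.2 against 2.22. CD40 and its proximal signalling proteins had a median of 0.12 over 20 genes (percentile 37.4). Birc2 had 3.56 against 2.19 FPKM there, Birc3 7.61 against 5.67, Tab2 8.58 against 6.54, and Tab1 13.6 against 17.7.

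The type I interferon response list was lower as a whole. Its median log2 ratio was -0.13 over 41 genes, below all random lists (percentile 0), and 7 of the 41 lay above the median of all genes. The antiviral 2'-5' oligoadenylate synthetase genes were the members past 2-fold. Oas1g (chromosome 5, 120876142 to 120887613) had 35.3 FPKM with anti-CD40 and 88.3 with IgG, 2.5-fold lower with an interval from 2.35 to 2.66. Oas1a had 64.7 against 137 FPKM, 2.12-fold lower with an interval from 2.02 to 2.22. These genes are close paralogs, but the sum of Oas1a, Oas1c and Oas1g was also lower, at 103 against 230 FPKM. Irf7, a transcription factor that amplifies interferon production, had 15.7 against 25.5 FPKM. Bst2, which encodes tetherin, went the other way with 309 against 193 FPKM. Interferon-gamma-inducible GTPases and regulators had a median of 0.23 over 13 genes (percentile 93.4) and did not stand apart, with Irf1 at 21.2 against 12.6 FPKM, Psmb9 at 46.5 against 32.7 and Gbp2 at 4.99 against 3.30.

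**Figure D3:**
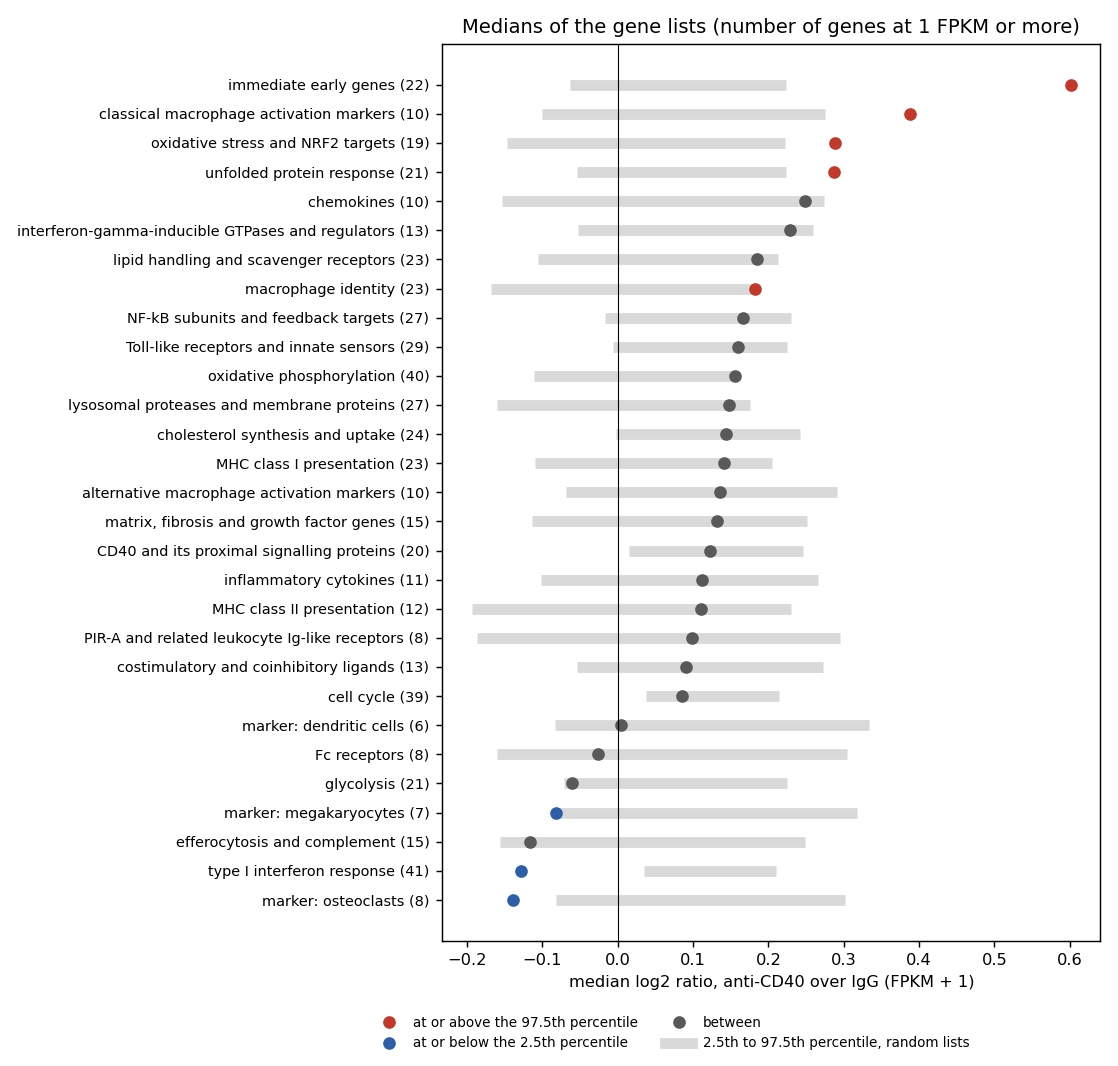
Median log2 ratio (anti-CD40 over IgG, on FPKM + 1) of each list with at least 5 genes at 1 FPKM or more; the number of genes is in parentheses, and grey bars span the central 95% of random lists matched on expression. Red and blue points stand apart, with immediate early genes at 0.60 and the type I interferon response at -0.13.

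In all, 8 of 29 lists with enough members stood apart, 5 higher and 3 lower. For lists of independently drawn genes, 1.45 would be expected. Members of a list can vary together and several lists share genes, so the number to expect here is not known. With random lists also matched on GC content and length, 4 stood higher and 2 lower. Oxidative stress and NRF2 targets had a median of 0.29 over 19 genes (percentile 99.7). Heme oxygenase Hmox1 had 162 against 108 FPKM, thioredoxin Txn1 292 against 192, and the quinone reductase Nqo1 1.67 against 0.937, whereas glutathione peroxidase Gpx1 had 2945 against 4258. The unfolded protein response list also had a median of 0.29, over 21 genes (percentile 99.9). Atf3, which the immediate early list holds too, had 162 against 106 FPKM, Herpud1 16.2 against 10.8 and Trib3 2.13 against 1.20. Ddit3, the gene of the stress factor CHOP, was lower with 87.1 against 129 FPKM. Macrophage identity genes had a median of 0.18 over 23 genes (percentile 97.9), with Cebpb at 111 against 72.3 FPKM, Sirpa at 334 against 244 and Cd14 at 333 against 244. That list no longer stood apart (percentile 92.4) when random lists were also matched on GC content and transcript length.

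Antigen presentation and surface receptors did not stand apart as lists. MHC class II presentation had a median of 0.11 over 12 genes (percentile 76.9), with H2-DMa at 51.2 against 35.0 FPKM, H2-DMb1 at 39.7 against 32.6 and the protease Ctss at 2254 against 1620. MHC class I presentation had a median of 0.14 over 23 genes (percentile 83.7). H2-D1 had 1795 against 1143 FPKM and H2-Q4 28.2 against 18.8, members of a family of close copies, while the immunoproteasome subunit Psmb10 had 226 against 343. Costimulatory and coinhibitory ligands had a median of 0.09 over 13 genes (percentile 33.8). Tnfsf9, the 4-1BB ligand, had 5.11 against 2.69 FPKM, Cd80 1.69 against 0.862, Icosl 3.54 against 2.24 and Cd274, the gene of PD-L1, 12.1 against 8.42. Cd86, named after its values were seen, had 0.649 against 0.989 FPKM, and the interval on that difference reaches from 0.962-fold to 2.45-fold lower. Toll-like receptors and innate sensors had a median of 0.16 over 29 genes (percentile 76.1), with Tlr2 at 40.9 against 24.1 FPKM and Clec4e at 28.2 against 18.6. Fc receptors had a median of -0.03 and a mean of 0.0022 over 8 genes (percentile 17.2), so median and mean differ in sign. The inhibitory Fcgr2b had 17.9 against 12.7 FPKM and the neonatal receptor Fcgrt 45.9 against 63.8.

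Alternative activation markers had a median of 0.14 over 10 genes (percentile 53.3), with Egr2 at 7.14 against 4.97 FPKM and Clec7a at 68.6 against 57.3. Matrix, fibrosis and growth factor genes had a median of 0.13 over 15 genes (percentile 68.8). Plau, the gene of urokinase, had 31.0 against 18.4 FPKM, Plaur 22.7 against 15.8, Pdgfb 11.6 against 7.48 and Tgfbi 36.5 against 25.4. Lipid handling and scavenger receptor genes had a median of 0.19 over 23 genes (percentile 94.6), with Fabp4 at 385 against 264 FPKM but lipoprotein lipase Lpl at 1007 against 1586. Efferocytosis and complement genes had a median of -0.12 over 15 genes (percentile 5.46). Mfge8, a bridge between apoptotic cells and phagocytes, had 998 against 1813 FPKM, properdin Cfp 149 against 221 and C1qb 1955 against 2623, while Gas6 had 194 against 156. Lysosomal genes had a median of 0.15 over 27 genes (percentile 94.0), with Atp6v1a, a subunit of the vacuolar proton pump, at 47.1 against 33.2 FPKM.

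Metabolic and proliferation lists lay within their random ranges. Glycolysis had a median of -0.06 over 21 genes (percentile 3.67), with Ldha at 144 against 98.8 FPKM and Pgk1 at 125 against 84.2, but Pfkp at 8.22 against 12.9. Oxidative phosphorylation had a median of 0.16 over 40 genes (percentile 97.3), with Cox5a at 237 against 137 FPKM and Ndufa1 at 48.4 against 25.7, but Ndufa2 at 544 against 1003. Cholesterol synthesis and uptake had a median of 0.14 over 24 genes (percentile 57.9), with Dhcr7 at 10.8 against 7.65 FPKM. The cell cycle list had a median of 0.09 over 39 genes (percentile 14.6), with Ube2c at 17.6 against 12.1 FPKM and Birc5 at 19.4 against 13.9, but Cdc25c at 0.784 against 1.29. Of genes often used as references, B2m had 619 against 562 FPKM and Actb 1766 against 1813. Both directions depend on the scaling: Actb is slightly higher with both libraries rescaled to the same sum, and B2m slightly lower after upper-quartile scaling. Gapdh had 9.16 against 13.1 FPKM, a low level in both libraries for a gene that has many processed pseudogenes.

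Markers of other cell types were mostly below 1 FPKM. Osteoclast markers had a median of -0.14 over 8 genes (percentile 0.77), with Dcstamp, a fusion protein of osteoclasts, at 2.02 against 3.33 FPKM, Acp5 at 7.07 against 8.77 and Ctsk higher at 46.0 against 38.1. This call held with matching on GC content and length (percentile 0.24) but was lost (percentile 9.685) without the filter on low values. Megakaryocyte markers had a median of -0.08 and a mean of 0.01 over 7 genes (percentile 2.44), with Gp1bb at 1.28 against 2.14 FPKM and Pf4 higher at 16.4 against 10.5. That call was lost with matching on GC content and length (percentile 5.92) and under other settings. Dendritic cell markers had a median of 0.0048 and a mean of -0.11 over 6 genes (percentile 10.9), with Tcf4 at 1.93 against 4.32 FPKM, Batf3 at 8.88 against 14.1 and Naaa at 13.8 against 9.96. Too few members for a percentile reached 1 FPKM among markers of monocytes (4, median 0.26), neutrophils and their precursors (2, median 0.05), B cells (1, median -0.20), T and NK cells (3, median -0.0078), erythroid cells (2, median -0.20), fibroblasts and stroma (2, median 0.03) and endothelial cells (1, median -0.27). No mast cell or basophil marker, 0 of 12, reached it. Haemoglobin genes summed to 1.45 FPKM with anti-CD40 and 3.80 with IgG. Ribosomal protein genes made up 16.1% of the summed values with anti-CD40 and 18.2% with IgG.

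Model-named and ribosomal protein genes left out, the genes with the highest ratios among those at 5 FPKM or more in either library were, after Il1b, Ctnnd1, Dynlt1f and Gdf15. Ctnnd1, the gene of p120 catenin, had 7.23 against 2.01 FPKM, 3.60-fold with an interval from 3.11 to 4.2. The stress cytokine Gdf15 (chromosome 8, 70629393 to 70632470) had 79.7 against 34.1 FPKM, 2.34-fold with an interval from 2.17 to 2.53. Dynlt1f had 25.8 against 9.42 FPKM, but it has close paralogs, and the sum of Dynlt1a, Dynlt1b, Dynlt1c and Dynlt1f was 146 against 127. Snhg6, Eif4e, Id3, Pim3 and Tomm5 were each between 2.08-fold and 2.44-fold higher.

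Among genes with the lowest ratios under the same rule, the histone gene H2aw (chromosome 11, 58954685 to 58955192) had 0.083 FPKM with anti-CD40 and 34.3 with IgG. It overlaps Trim17, which was higher with 14.5 against 7.06 FPKM, a partner named after its values were seen, and the 2 cannot be separated where reads fall on both, since the strand setting is not given in the sources used here. Derpc, with 2.91 against 7.36 FPKM, likewise overlaps Chtf8, which was higher with 17.0 against 9.04. The long noncoding RNA Neat1 (chromosome 19, 5824708 to 5845480), a scaffold of nuclear paraspeckles, had 132 against 725 FPKM, 5.51-fold lower with an interval from 5.35 to 5.68. Lsp1, which encodes an actin-binding protein of leukocytes, had 198 against 405 FPKM, and the LIM-domain gene Crip1 859 against 1768. Nrp and Mrpl58 had 3.98 against 12.5 FPKM and 27.0 against 55.6. The liver transcripts Alb (9.56 against 21.1 FPKM), Apoa2 (6.15 against 13.9) and Mup13 (7.48 against 25.2) completed this set; Mup genes are near-identical copies, and other hepatocyte transcripts were lower along with them.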

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

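With 1 library per group, no alternative could leave out a replicate, and none measures the spread between cultures. The GC and length alternatives and the mean of the sums were chosen after the data were seen, the others before. Of 29 lists, 21 kept their side of the percentile limits under every alternative that gave a value, among them immediate early genes, classical activation markers, NRF2 targets, the unfolded protein response and the type I interferon response. Of 148 named genes, 139 kept their sign under both pseudocounts and every scaling, the exceptions being Actb, B2m, Cd28, Gm15448, Lilra5, Lilrb4a, Pira1, Pira2 and S100a4. The count of 24 genes higher and 30 lower became 88 and 75 with a pseudocount of 0.1, 4 and 10 with 5, 13 and 54 after centring, 15 and 54 after upper-quartile scaling, and 14 and 19 with a filter at 5 FPKM, which leaves fewer genes and too few members in the interferon-gamma, dendritic cell and megakaryocyte lists. Rescaling to the mean of the sums gave 30 and 24. TPM-like sums, which also multiply the values by 1.89 and 1.83 against the same pseudocount and filter, gave 61 and 41, and removing the GC or the length trend, which also centres the ratios, gave 15 higher each and 41 and 42 lower. Dropping the filter left 24 and 30.

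Under the pseudocounts and scalings, 701 log2 ratios of named genes moved by no more than 0.5 of the width of their counting interval, 187, from 73 genes, moved further or had no interval, and 0 of the genes past 2-fold changed sign. Several list medians changed sides as well, and the cause was not tested. The interferon-gamma list came to stand apart with a pseudocount of 0.1 (0.40) and of 5 (0.13), the chemokines with a pseudocount of 5 (0.21) and no filter (0.11), and oxidative phosphorylation with a pseudocount of 5 (0.15) and the mean of the sums (0.20). Efferocytosis and complement did so with no filter (-0.11) and unmatched random lists (-0.12), and glycolysis under the same settings (-0.0608 in both). Macrophage identity, at 0.18 in each case, lost its place with no filter, with unmatched lists and with matching on GC and length. Osteoclast markers lost theirs with no filter (-0.00623). Megakaryocyte markers lost theirs with a pseudocount of 0.1 (-0.0917), TPM-like sums (-0.00476), the mean of the sums (-0.0390), no filter, where the median turned to 0.0128, unmatched lists (-0.0825) and matching on GC and length (-0.0825). Summing rows that share a symbol moved nothing, as no symbol is shared, and size factors were not run, since the table holds no counts. Depth limits the low genes most: the interval on the Cd40 ratio spans 0.785 to 1.64.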

Other observations

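The tests of overlapping genes, of the NF-kB list and of GC and length trends at the lower genes were chosen only after the results were seen, and Rps15, Rpl21, Malat1, Lyz2, Fth1, Trf, Ass1, Cyp2e1 and the overlapping partners were named after their values were seen. Among abundant ribosomal protein genes, Rps15 had 3992 FPKM with anti-CD40 and 8897 with IgG and Rpl21 had 148 against 324, although the median log2 ratio of 91 such genes was 0.02. Malat1, a nuclear noncoding RNA that lies next to Neat1, was higher with 53.0 against 34.6 FPKM, opposite to Neat1. Lyz2 and Fth1, highly expressed in macrophages, had 13423 against 11326 and 33260 against 28724 FPKM.

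Hepatocyte transcripts made up 7 of the 30 genes at least 2-fold lower with anti-CD40 (Alb, Apoa1, Apoa2, Mup13, Mup20, Mup7 and Cyp2e1). Of 33 further hepatocyte genes listed before the test, 24 reached 0.5 FPKM in either library, 23 of these were lower with anti-CD40, and their median log2 ratio without a pseudocount was -1.29, close to -1.14 for Alb. Trf (140 against 151 FPKM) and Ass1 (3.57 against 2.72) are genes that macrophages also express and did not share that size. Only 2 of 14 listed heart muscle genes reached 0.5 FPKM, which argues against heart tissue as the source. A small share of liver RNA or of reads from a liver library, larger in the IgG library, is a candidate explanation, while an effect of the antibody on these genes was not tested and stays open.

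The 30 genes at least 2-fold lower with anti-CD40, hepatocyte transcripts included, were set against composition and annotation. The log2 ratio was slightly lower at higher GC content (Spearman rho -0.20 across genes, with medians of 0.16 in the lowest and 0.02 in the highest of 5 equal groups) and hardly varied with length (rho 0.05). For 26 of the 30 genes, GC content and length were known. There the fitted trends lay at a median of 0.0110 (GC content) and -0.0131 (length) from the median of all genes and at -0.12 at the lowest. The genes themselves, chosen for low ratios, had a median of -1.21, so smooth trends this small do not reach their size. Such trends cannot show a sequence bias particular to single genes, and none was tested. Of the 30 genes, 5 overlap a gene that differs the other way (Adnp with Gm20716, Plpp6 with 4430402I18Rik, H2aw with Trim17, Derpc with Chtf8, Prc1 with Rccd1), against a mean of 0.332 and at most 4 in random lists. So do 5 of the 24 genes at least 2-fold higher, for which no random lists were drawn. Among the higher genes, Gm20716, 4430402I18Rik and Rccd1 are partners already counted from the lower side. For the 5 lower genes, reads assigned differently between overlapping genes are a candidate explanation, but too few of the 30 have such a partner for it to cover the set, and anti-CD40 treatment stays open for the rest.

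The immediate early list was higher by a median of 0.60 and stayed at percentile 100 with matching on GC content and length, which argues against these properties as the cause. Immediate early genes also respond to handling of cells, and 9 heat shock genes had a median log2 ratio of 0.21 (percentile 85.25), neither high enough to stand apart nor at or below the median of all genes. The NF-kB list, expected to be higher if CD40 signalling were active, was at percentile 89.08 with the same matching. Handling and anti-CD40 treatment therefore cannot be told apart, because each condition is a single library.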
